A study of Mus musculus with 6 samples.

How the data were processed

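6 libraries of total RNA from the mouse line TIBx were used, 3 of the parental genotype WT and 3 of the genotype DNAJ-PKAc, grouped by the genotype and replicate letter in the labels. Cells were grown in DMEM with serum and added glutamine, and libraries were made with a stranded total RNA kit, per the labels' protocols. The deposited table holds expected counts per gene symbol for 24054 genes, 1 column per library and not normalized, per the file headers and from the column totals, which differ. STAR 2.5.2b, RSEM 1.3.0 and the build mm10 are named without a role, per the submitters' processing notes. The gene annotation, read trimming, filters and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes, and of near-identical paralogs, could be shared, and such genes are called uncertain. Between 1.52% and 1.68% of values per library were not whole. Columns were matched to samples by their names.

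Expected counts were rounded to whole numbers. Genes were kept by filterByExpr with a minimum count of 10 (10975 genes), and 10098 genes had no read in any library. Libraries were scaled by TMM, and edgeR 4.0.16 in R 4.3.3 fitted a quasi-likelihood model with robust dispersions and the group as the only term. Every adjusted p for a gene is from that 2-sided test with Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05, unless another tool is named. Differences are DNAJ-PKAc minus WT, and CPM values are TMM-scaled, except those of Malat1 and the summed leukocyte markers, which use the plain totals. A fold against a group with 0 counts was computed against a floor of 3 counts over the group, and with 1 to 3 counts the ratio of counts is given with a 95% interval. Such intervals and floors cover counting error only, and the labels name no molecular identifiers. Totals ran from 8095549 to 9969590 per library, so 1 CPM is about 8 to 10 counts.

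The test, the 31 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Named were Prkaca, Dnajb1 and the genes between them, 7 genes of glutamine and nitrogen metabolism, the 8 calls of largest fitted change in each direction with at least 5 CPM in the higher group, no overlap between groups and no predicted-model name, and in each list described the 2 members of smallest adjusted p with up to 2 more. Some genes that this rule names are not reported here. Alb and Hnf4a, the window regions and the genes opening the other observations were chosen after their values were seen. Lists with at least 3 tested genes were tested by camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and adjusted over the 26 lists. Counts "adjusted over the list alone" adjust the gene p-values within the list. The lists hold the interval between the fusion partners, PKA subunits, the CREB response, markers of human fibrolamellar tumours, lists of metabolism and stress, and lists of cell identity, proliferation, p53, interferon and other cell types.

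Alternatives were RLE and upper-quartile factors, no filter, a stricter filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, dispersions without the robust option, the replicate letter as a block, each library left out in turn, structural RNA left out of library sizes, a threshold of 0.01, and for lists an estimated correlation, camera on ranks and fry. Leaving out WT B and DNAJ-PKAc C together, and limma-voom with library quality weights, were added after the data were seen. Coordinates are 1-based, from NCBI RefSeq genes on GRCm38.p6, the assembly of mm10, and 10931 of the 10975 genes matched. GC content and length came from the longest GENCODE transcript of each symbol.

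The tests were tested on simulated counts with the means and library sizes of these libraries (10975 genes simulated, 10895 tested). edgeR recovered 14 of 100 genes changed 2-fold and 82 of 100 changed 4-fold and called 10 unchanged genes, so many 2-fold changes are missed at this size. DESeq2 recovered 35 and 92, and limma-voom 10 and 81. Camera called a list of 30 genes shifted 1.5-fold and 0 of 20 unshifted lists. The simulated genes were drawn independently, whereas the estimated correlation within the real lists reached 0.884, for cell cycle. The 0 of 20 therefore does not bear on false calls of correlated lists. The test along the genome was tested with a log2 shift of 0.5 planted on 120 neighbouring genes, in 100 draws each of 2 kinds of noise. Single earlier draws with normal noise had come out on both sides of 0.05, which is why many were run. With normal noise the shift was detected in 60 draws, and with the measured values at permuted positions in 98. With no shift planted, 2 and 6 draws passed. All 3 shifted windows passed a median of 0.2 in 75 and 76 draws, beside a median of 8 and 1 unshifted windows that did, so regions were described only where at least 3 neighbouring windows passed 0.2 in every DNAJ-PKAc library. Exceptions were the histone window and windows of larger median on chromosomes 1 and 6, which were singled out after they were seen.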

Results

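Total RNA was sequenced from TIBx, a mouse line whose labels give the cell type as liver BNL 1ME A.7R.1, in the parental state (WT) and in a line of genotype DNAJ-PKAc. DNAJ-PKAc is the fusion of the start of the co-chaperone DNAJB1 with the catalytic subunit of protein kinase A, the defining lesion of fibrolamellar carcinoma of the liver. Each group had 3 libraries, replicates A to C, and the totals ran from 8095549 to 9969590 expected counts per library. The labels do not say that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. DNAJ-PKAc A and B correlated at 0.993 across genes but differed by more than sampling noise, as did WT A and C, and all 6 libraries were counted separately. The first principal component of log2 CPM carried 55.6% of the variance. On it DNAJ-PKAc A and B scored 52.8 and 55.4, the WT libraries between -47.8 and -23.5, and DNAJ-PKAc C -6.89. The second, with 26.5%, set DNAJ-PKAc C apart at -61.5. WT B differed in its RNA makeup: the ribosomal precursor Rn45s took 2.66% of its counts, against 0.912% to 1.05% in the other libraries, and the nuclear RNA Malat1 stood at 10410 CPM, against 1065 to 4639.

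**Figure D1:**
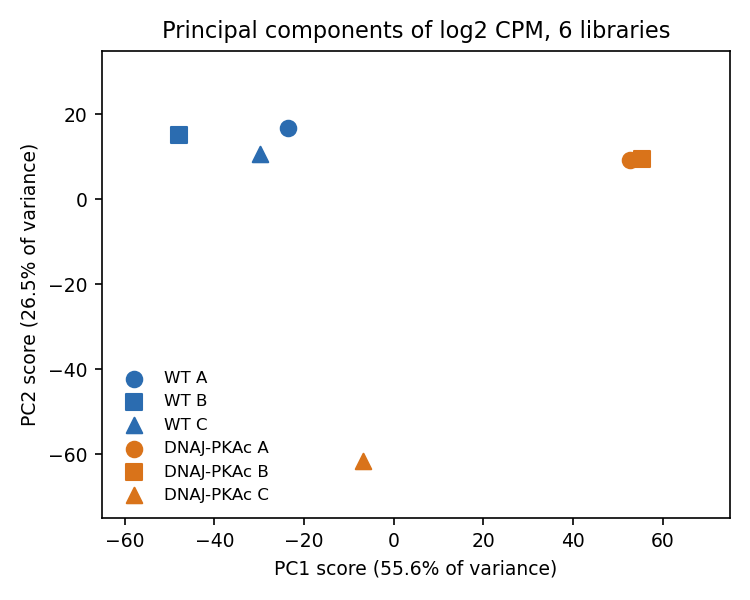
Scores of the 6 libraries on the first 2 principal components of log2 CPM (PC1, 55.6% of the variance, and PC2, 26.5%), colour for the group and marker shape for the replicate. DNAJ-PKAc A and B lie together at PC1 scores of 52.8 and 55.4, and DNAJ-PKAc C lies apart at a PC2 score of -61.5.

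The comparison asked how the transcriptome of cells with the fusion kinase differed from that of their parents, and the genes of the fusion were read first as a check of the labels. With a single line per genotype, a difference between the lines cannot be separated from an effect of the fusion in any result below. Prkaca, which encodes the kinase part (chromosome 8, 83972978 to 83996444 in mm10), was at 63.6, 87.6 and 79.2 CPM in WT A, B and C and at 131, 120 and 95.7 CPM in DNAJ-PKAc A, B and C. All 3 fusion libraries lay above all 3 WT libraries, a fold of 1.51 (log2 0.59, SE 0.19), but the difference missed the threshold (edgeR quasi-likelihood test, adjusted p = 0.154). Without DNAJ-PKAc C the log2 difference was 0.71 and passed it (adjusted p = 0.0242). Dnajb1 (83608175 to 83612653) was at 70.9, 63.7 and 58.0 CPM in WT and at 76.0, 72.2 and 44.4 CPM in DNAJ-PKAc, with a log2 difference of 0.00 (SE 0.23, adjusted p = 0.999). Counts per gene do not show the junction of the fusion, which was not examined here.

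Between Dnajb1 and Prkaca on the same chromosome lie 7 tested genes, the stretch that a deletion joining the 2 partners would remove. Lphn1 (now Adgrl1, a latrophilin adhesion receptor, 83900098 to 83941954) fell 30.5-fold, from 5.07 ± 1.37 CPM (SD, n = 3) to 0.156 ± 0.0797 CPM (edgeR adjusted p = 0.00539). Ptger1, a prostaglandin E receptor gene at low counts, had a log2 difference of -1.89 (adjusted p = 0.0902), and Gipc1 one of -0.40 (0.298). Cd97 (Adgre5) was at -0.60 (0.355), Ddx39 at 0.58 (0.506) and the histone chaperone gene Asf1b at 1.05 (0.390), with the last 2 high in DNAJ-PKAc A and B and below WT in C. Without DNAJ-PKAc C, Ptger1 (adjusted p = 0.0143), Ddx39 (0.00869) and Asf1b (0.0037) also passed. Ptger1 overlaps another gene, and Ddx39 overlaps Cd97, and the strand setting of the counting is not given in the sources used here, so reads of overlapping genes could be shared. As a list the 7 genes were lower (camera adjusted p = 0.00419; adjusted p = 0.223 with an estimated correlation), with 0 rising and 1 falling over all genes tested and 3 falling adjusted over the list alone. Of the 7 genes 5 lay below 0 and 2 above. The 4 with a mean of at least 10 CPM had a median log2 difference of 0.09. That cut leaves out Lphn1, Ptger1 and Cd97, which all lay below 0. Over the 3 DNAJ-PKAc libraries together, the list call therefore does not show a fall shared by every gene of the stretch. In DNAJ-PKAc C alone, the genes of the stretch named here all lay below every WT library. The list medians were -0.49, -0.27 and -1.05 in DNAJ-PKAc A, B and C. The call was lost without DNAJ-PKAc C (camera adjusted p = 0.219), without WT B and DNAJ-PKAc C (0.265) and with library quality weights (0.142).

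**Figure D2:**
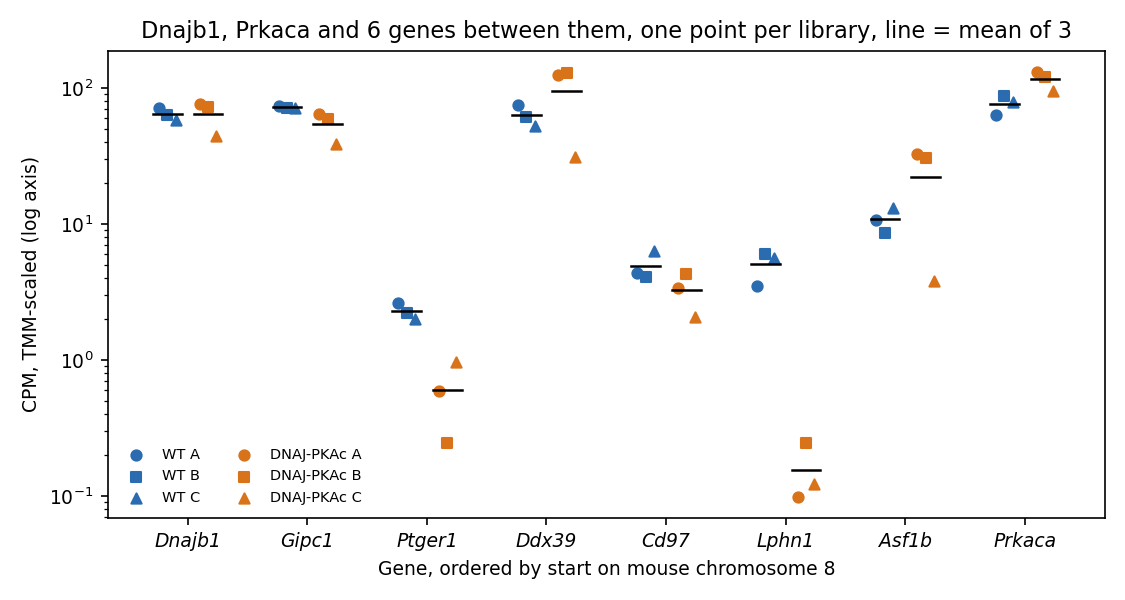
TMM-scaled CPM (log axis) of Dnajb1, Prkaca and 6 genes between them, ordered by start on chromosome 8, with 1 point per library and a line at the mean of 3. Prkaca lies higher in all 3 DNAJ-PKAc libraries, Lphn1 lies lower at 0.156 CPM against 5.07, and Ddx39 and Asf1b are split, with DNAJ-PKAc C below WT.

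Across the 10975 genes tested, 385 changed, 150 higher and 235 lower in DNAJ-PKAc (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 105 rose and 209 fell at least 2-fold. All 385 had groups that did not overlap, as did 3171 of the genes tested, or 28.9%, against 10% by chance for 3 libraries against 3. Passing the test nearly fixes this for the 385, and the 10% takes the libraries as exchangeable, so neither adds support to the calls. With upper-quartile scaling the split was 114 higher and 295 lower. Leaving out WT A, B or C gave 85, 110 and 91 genes and leaving out DNAJ-PKAc A or B gave 78 and 77, whereas leaving out DNAJ-PKAc C gave 2808 (1587 higher and 1221 lower) and leaving out both WT B and DNAJ-PKAc C, chosen after the data were seen, gave 5336. The last choice kept the closest pair of each group (r of 0.987 for WT A and C and 0.993 for DNAJ-PKAc A and B). A smaller spread within groups, and so more calls, was built into it.

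Among genes of at least 5 CPM in the higher group, the 8 calls of largest fitted change in each direction were named. Pde4b, a cyclic AMP phosphodiesterase gene, had 0 counts over the WT libraries and 552 over the DNAJ-PKAc libraries (21.5 ± 13.4 CPM, SD, n = 3), and was at least 186-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.0145). Jam2, a junctional adhesion molecule gene, had 1 count against 141, a ratio of 143 with a 95% counting interval of 25.2 to 5680. Afp, the fetal liver protein alpha-fetoprotein, rose 41.2-fold (log2 5.36, SE 1.11, adjusted p = 0.0252) to 6.68 ± 4.01 CPM (SD, n = 3), and Fst, the activin antagonist follistatin, rose 27.3-fold. The growth factor gene Fgf7 rose 11.2-fold to 106 ± 72.0 CPM (SD, n = 3), with 189 CPM in DNAJ-PKAc C and 60.4 and 67.7 in A and B. Slc22a23 rose 9.15-fold (log2 3.19, SE 0.26, adjusted p = 0.00279), Eepd1 8.75-fold, and Ramp3, which encodes a partner of the calcitonin receptor family, 8.48-fold. Ramp3 was at 198 and 186 CPM in DNAJ-PKAc A and B but at 44.4 CPM in C, against a WT mean of 16.8 CPM. Among the decreases, Ica1 had 142 counts in WT and 0 in DNAJ-PKAc, at least 46.7-fold lower. Eya4, a transcriptional coactivator gene, had 776 counts against 2 (ratio 383, 95% counting interval 106 to 3170), Arrdc4 had 421 against 2 (ratio 208, interval 57.2 to 1720), and the metalloprotease gene Adam19 had 205 against 1 (ratio 202, interval 35.9 to 8030). The bone matrix gene Dmp1 fell 262-fold, and the laminin chain gene Lama5 fell 146-fold, from 152 ± 80.8 to 1.05 ± 0.473 CPM (SD, n = 3; log2 -7.18, SE 0.52, adjusted p = 0.00188). Tenm3 fell 93.2-fold and the guanylate-binding protein gene Gbp9 fell 51.6-fold (adjusted p = 0.00137). Leaving out any 1 library but DNAJ-PKAc C left between 77 and 110 calls over all genes, and some of the calls named here were lost with it. Without WT B the calls of Pde4b, Jam2, Afp, Fst, Fgf7, Eepd1, Ramp3 and Ica1 were lost, without WT A those of Afp, Fst, Fgf7, Eepd1 and Ramp3, without WT C those of Afp, Fgf7, Eepd1 and Ramp3, without DNAJ-PKAc A those of Afp, Fst, Ramp3 and Adam19, and without DNAJ-PKAc B those of these 4 and Eepd1, with an adjusted p of at most 0.143 (Ramp3 without WT C). Where the call was lost, the log2 difference ran from 2.78 to 3.29 for Ramp3 (3.08 with all 6 libraries), from 3.32 to 3.65 for Fgf7 (3.48), from 2.99 to 3.29 for Eepd1 (3.13), from 4.49 to 5.53 for Fst (4.77) and from 4.81 to 6.57 for Afp.

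Of 31 gene lists fixed before the data were examined, 26 had enough tested genes, and 11 lists were higher and 3 were lower in DNAJ-PKAc by the camera test with a preset correlation of 0.01. None of the 14 passed with an estimated correlation. For the p53 target list and the genes between Dnajb1 and Prkaca the estimate, at -0.0492 and -0.0232, lay below the preset 0.01. Their loss was not due to a higher correlation, so failing this setting does not by itself show correlated genes. Cholesterol synthesis genes had the smallest camera p of the higher lists with all 6 libraries, but not without WT A, WT C or DNAJ-PKAc C. In that list 8 of 23 rose and 0 fell over all genes tested, and 16 rose adjusted over the list alone. The median log2 difference was 0.74 (camera adjusted p = 9.2e-09, and adjusted p = 0.223 with an estimated correlation). Pmvk rose 3.02-fold (29.3 ± 2.19 to 88.4 ± 16.7 CPM, SD, n = 3; edgeR adjusted p = 0.0092), Nsdhl 2.49-fold, the lanosterol synthase gene Lss 2.27-fold and Idi1 1.96-fold. The list medians against the WT mean were 0.67, 0.71 and 0.92 in DNAJ-PKAc A, B and C. Without WT B 3 of its genes rose, without any 1 of WT A, WT C, DNAJ-PKAc A or B 1 rose, and without DNAJ-PKAc C 13 rose. Genes of the CREB and cyclic AMP response were higher too (4 of 22 rose and 0 fell, 5 rose adjusted over the list alone; camera adjusted p = 0.00153; adjusted p = 0.266 with an estimated correlation). The list medians were 0.58, 0.49 and 0.86 in DNAJ-PKAc A, B and C. In that list 7 genes rose without DNAJ-PKAc C and 1 without any other 1 library. The 4 genes were Pde4b, the orphan nuclear receptor genes Nr4a2 (3.03-fold, edgeR adjusted p = 0.0162) and Nr4a1 (2.95-fold, 0.0389), and Id1 (3.36-fold, 0.0276). Pmvk, Nsdhl, Lss, Idi1, Nr4a2, Nr4a1 and Id1 each lost the call without at least 1 WT library or without DNAJ-PKAc A or B, with an adjusted p of at most 0.164, for Nr4a1 without WT C. Among PKA subunits and inhibitors, 0 of 12 rose and 1 fell, the inhibitor gene Pkig (log2 -0.86, SE 0.17, edgeR adjusted p = 0.0397; lost without any 1 of WT A, B, C, DNAJ-PKAc A or B, at most 0.17), while Prkar1b was at -1.47 (0.0546). Adjusted over the list alone, 2 rose and 3 fell. Without DNAJ-PKAc C 3 rose and 3 fell over all genes tested. That list was not called (camera adjusted p = 0.711), and its median of 0.08 lay above 0 while its mean of -0.09 and its test pointed down.

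The lists of the citrate cycle, nuclear oxidative phosphorylation and proline and polyamine genes were higher with few single calls. In the citrate cycle list 2 of 33 rose and 0 fell (camera adjusted p = 0.00153; adjusted p = 0.376 with an estimated correlation), and adjusted over the list alone 2 rose and 1 fell. Its medians were 0.36, 0.44 and 0.20 in DNAJ-PKAc A, B and C. Without DNAJ-PKAc C 9 of its genes rose and 2 fell. Without any other 1 library 1 rose. Pcx, the anaplerotic enzyme pyruvate carboxylase, rose 5.47-fold, from 10.6 ± 1.19 to 58.2 ± 6.85 CPM (SD, n = 3; log2 2.45, SE 0.17, edgeR adjusted p = 0.00188). Cs, citrate synthase, rose 1.81-fold (adjusted p = 0.0273; not past the threshold without any 1 of WT A, B, C, DNAJ-PKAc A or B, at most 0.143). Nuclear oxidative phosphorylation genes had a median log2 difference of 0.38 with 66 of 70 above 0, and 0 rose or fell by edgeR over all genes tested or adjusted over the list alone (camera adjusted p = 2.0e-08; adjusted p = 0.576 with an estimated correlation). Ndufa12 was at 0.81 (edgeR adjusted p = 0.0751) and Atp5b at 0.82 (0.0948). The medians were 0.40, 0.50 and 0.34 in DNAJ-PKAc A, B and C, and the WT B median of that list lay at -0.34 against the WT mean, away from 0.18 and 0.15 in WT A and C. Without WT B the list's median log2 difference was 0.21, with 0 genes rising (camera adjusted p = 0.000496), and without DNAJ-PKAc C it was 0.42, with 18 rising and 0 falling. Proline and polyamine genes were higher with 1 of 16 rising, both over all genes tested and adjusted over the list alone, and 0 falling: Smox, spermine oxidase, 4.24-fold (edgeR adjusted p = 0.00769), while Sat1 was at log2 0.87 (0.118). That list had a camera adjusted p of 0.0137 (adjusted p = 0.353 with an estimated correlation), and its call was lost without WT B (camera adjusted p = 0.0579) and without WT B and DNAJ-PKAc C (0.0773). Without DNAJ-PKAc C 4 of its genes rose and 1 fell.

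Glutamine and glutamate genes, the theme of the series title, were not called as a list (camera adjusted p = 0.0775; adjusted p = 0.576 with an estimated correlation): 0 of 27 rose or fell, over all genes tested and adjusted over the list alone, with 20 above 0. Of single genes fixed for this question, the glutamine synthetase gene Glul differed by log2 0.02 (SE 0.20, edgeR adjusted p = 0.962), the glutamine transporter gene Slc1a5 by 0.25 (0.501), Asns by 0.16 (0.681), Oat by 0.41 (0.289) and Ass1, some of whose reads were shared with other genes, by 0.76 (0.126). Cps1 was below the count filter. Ctps and Ppat, which use glutamine for nucleotide synthesis, were at 0.71 (0.0604) and 1.01 (0.0858). The list was called without WT B (camera adjusted p = 0.0253), with 0 genes rising or falling, without WT B and DNAJ-PKAc C (0.0468), with 10 rising and 2 falling, and with library quality weights (0.0283). Without DNAJ-PKAc C it was not called (0.115), with 6 rising and 1 falling. In the urea cycle and arginine list, 1 of 6 rose and 0 fell, and 2 rose adjusted over the list alone (camera adjusted p = 0.151). Without DNAJ-PKAc C 3 rose and 1 fell. With all 6 libraries the gene that rose was Arg2, mitochondrial arginase, 8.31-fold to 15.3 ± 6.95 CPM (SD, n = 3; edgeR adjusted p = 0.0187; not past the threshold without any 1 of WT A, B, C, DNAJ-PKAc A or B, at most 0.0883).

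Several higher lists were split within the fusion group, while the p53 target list, given last, was not. Cell cycle genes had median log2 values of 1.84 and 1.91 against the WT mean in DNAJ-PKAc A and B and of -1.08 in C. By edgeR 0 of 38 rose or fell, over all genes tested and adjusted over the list alone (camera adjusted p = 0.00252; adjusted p = 0.732 with an estimated correlation), and Cdk4 was at log2 0.80 (edgeR adjusted p = 0.0912) and Ccne1 at 1.49 (0.108). Without DNAJ-PKAc C, 36 of the 38 rose, as did 15 genes of the nucleotide synthesis list, 10 of heat shock, 13 of NRF2 and glutathione and 8 of serine and one-carbon metabolism, with 0 falling in each. The list call was lost without DNAJ-PKAc A (camera adjusted p = 0.101) or B (0.102). Nucleotide synthesis medians were 0.55, 0.66 and -0.14 in A, B and C (camera adjusted p = 0.00252; adjusted p = 0.576 with an estimated correlation). Of its 25 genes 0 rose and 0 fell, 3 rose adjusted over the list alone, and Ctps and Uck2 (log2 0.59, edgeR adjusted p = 0.0809) led it. Heat shock medians were 0.63, 0.75 and -0.08 (0.00419; adjusted p = 0.576 with an estimated correlation). There 0 of 16 rose or fell and 4 rose adjusted over the list alone, with Dnaja1 at log2 0.74 (edgeR adjusted p = 0.0955) and Fkbp4 at 0.85 (0.0977). NRF2 and glutathione medians were 0.55, 0.67 and -0.05 (0.00299; adjusted p = 0.304 with an estimated correlation). In that list 2 of 26 rose and 0 fell, and 6 rose adjusted over the list alone. Ftl1, ferritin light chain, rose 1.94-fold and Txnrd1, thioredoxin reductase, 2.56-fold, and both calls were lost without WT A, B or C or DNAJ-PKAc A or B, with an adjusted p of at most 0.158. Serine and one-carbon medians were 0.51, 0.58 and 0.12 (0.0265; adjusted p = 0.576 with an estimated correlation), with 0 of 18 rising or falling, over all genes tested and adjusted over the list alone. Slc25a32 was at log2 0.60 (edgeR adjusted p = 0.092) and Psat1 at 0.56 (0.152), and the list call was lost without WT B (camera adjusted p = 0.0579), WT C (0.114), DNAJ-PKAc A (0.0712) or DNAJ-PKAc B (0.0743). The p53 target medians were 0.35, 0.43 and 0.22 (0.00656; adjusted p = 0.223 with an estimated correlation), with 1 of 18 rising and 0 falling, and 2 rising adjusted over the list alone, and 6 rising and 1 falling over all genes tested without DNAJ-PKAc C. With all 6 libraries the gene that rose was Plk2, a polo-like kinase gene (3.45-fold, edgeR adjusted p = 0.0102; 0.0569 without WT B and 0.0586 without WT C), while Fas was 2.83 times its WT level (0.079).

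Interferon response genes had the smallest p of the lower lists: 10 of 33 fell and 0 rose over all genes tested, 20 fell adjusted over the list alone, and the median log2 difference was -0.87 (camera adjusted p = 4.2e-13; adjusted p = 0.310 with an estimated correlation). Ifit3, some of whose reads were shared with other genes, fell 18.0-fold, from 157 ± 41.0 to 8.74 ± 1.91 CPM (SD, n = 3; edgeR adjusted p = 0.00137). Gbp2 fell 6.13-fold (61.7 ± 12.1 to 10.0 ± 2.76 CPM), the RNA sensor gene Ifih1 5.92-fold and the oligoadenylate synthetase gene Oas2 4.45-fold, the last with an adjusted p of 0.0537 without DNAJ-PKAc A and 0.0551 without DNAJ-PKAc B. The list medians against the WT mean were -0.57, -0.66 and -1.63 in DNAJ-PKAc A, B and C. Without DNAJ-PKAc C 16 of its genes fell and 1 rose, and without another library between 3 (DNAJ-PKAc B) and 8 (WT C) fell. Hypoxia genes were lower as well: 4 of 21 fell and 0 rose, 9 fell adjusted over the list alone, and the medians were -0.53, -0.57 and -0.58 (camera adjusted p = 3.8e-05; adjusted p = 0.223 with an estimated correlation). Without DNAJ-PKAc C 10 of its genes fell and 1 rose, and without another library 2 fell, or 3 without WT C. The carbonic anhydrase gene Car9 fell 20.9-fold, from 37.8 ± 6.65 to 1.81 ± 0.555 CPM (SD, n = 3; edgeR adjusted p = 0.00137), and the collagen prolyl hydroxylase gene P4ha2 fell 2.75-fold (0.00753). Ankrd37 fell 3.92-fold and the endoplasmic reticulum oxidase gene Ero1l 2.72-fold, and both calls were lost without WT A or B or DNAJ-PKAc A or B, and that of Ero1l also without WT C, with an adjusted p of at most 0.174.

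**Figure D3:**
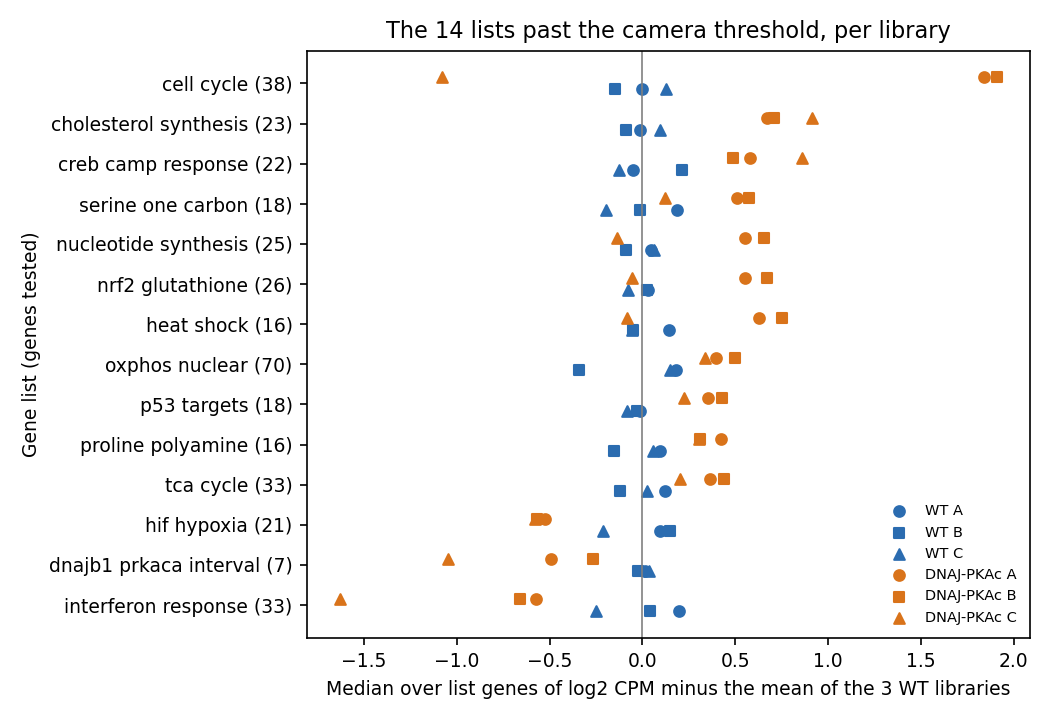
Median log2 CPM of each list's genes minus the mean of the 3 WT libraries, 1 point per library, for the 14 lists past the camera threshold (genes tested in parentheses). The cell cycle list is split, at 1.84 and 1.91 in DNAJ-PKAc A and B and -1.08 in C, while hypoxia lies between -0.58 and -0.53 in all 3.

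Other metabolic lists were not called. In glycolysis 0 of 22 rose and 1 fell, Eno2 (log2 -1.31, SE 0.22, edgeR adjusted p = 0.0267; lost without WT A, WT B, DNAJ-PKAc A or B, at most 0.128), while the lactate transporter gene Slc16a1 was at 0.79 (0.140; camera adjusted p of the list 0.555). In fatty acid oxidation 1 of 20 rose and 0 fell, Echs1 (2.12-fold, edgeR adjusted p = 0.0287; lost without any 1 of WT A, B, C, DNAJ-PKAc A or B, at most 0.126), and Acadl was at -0.67 (0.0899; camera 0.387). In fatty acid synthesis (0 of 17; camera adjusted p = 0.146) Fads2 was at 0.71 (edgeR adjusted p = 0.0853) and Elovl6 at 0.56 (0.116), and in mitochondrial biogenesis (0 of 20; camera adjusted p = 0.195) Tfam was at 0.69 (0.124) and Ssbp1 at 0.71 (0.145). In the ATF4 stress response list 1 of 27 rose and 0 fell, the hormone gene Fgf21 (22.9-fold, 4 counts against 96, edgeR adjusted p = 0.0444; lost without any 1 of WT A, B, C, DNAJ-PKAc A or B, at most 0.148), and the list was not called (camera adjusted p = 0.276). Adjusted over each list alone, these 5 lists gave the same number of calls. The counts over all genes tested differed without DNAJ-PKAc C: 4 rose and 2 fell in glycolysis, 1 rose and 5 fell in fatty acid oxidation, 2 rose and 0 fell in fatty acid synthesis, 5 rose and 0 fell in mitochondrial biogenesis and 4 rose and 5 fell in the ATF4 list. Acadl passed without DNAJ-PKAc C (edgeR adjusted p = 0.0232). Without WT B and DNAJ-PKAc C, 1 rose and 8 fell in fatty acid oxidation and 5 rose and 6 fell in the ATF4 list. The median of the ATF4 list was 0.16 with all 6 libraries and -0.09 without DNAJ-PKAc C. The log2 difference of Fgf21 ran from 3.65, without DNAJ-PKAc C, to 4.873 over all its alternatives. Mitochondrial biogenesis was called as higher without WT B and DNAJ-PKAc C (camera adjusted p = 0.0395), with 8 genes rising and 1 falling, and with library quality weights (0.0365).

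Genes reported for human fibrolamellar tumours were not called as a list (camera adjusted p = 0.151), and 0 of 14 passed over all genes tested, with 3 falling adjusted over the list alone. Car12 was at log2 -1.83 (edgeR adjusted p = 0.0875) and Sox9 at -1.67 (0.0955). Without DNAJ-PKAc C 1 gene of that list rose and 2 fell, with Car12 past the threshold (edgeR adjusted p = 0.0222), and without WT B and DNAJ-PKAc C 2 rose and 7 fell. Hepatocyte transcripts were almost absent from both lines. Of 35 hepatocyte genes 2 passed the count filter, Afp, which rose, and the keratin gene Krt8, which fell 8.52-fold from 7.70 ± 0.359 to 0.873 ± 0.665 CPM (SD, n = 3; edgeR adjusted p = 0.036; lost without any 1 of WT A, B, C, DNAJ-PKAc A or B, at most 0.131). Alb and Hnf4a had 0 counts over the 6 libraries. In the progenitor and biliary list 0 of 4 passed, with 1 falling adjusted over the list alone (camera adjusted p = 0.550) and 1 falling over all genes tested without DNAJ-PKAc C, and Sox4 was at 0.77 (edgeR adjusted p = 0.188). In the mesenchymal and matrix list 3 of 37 rose and 0 fell, 5 rising adjusted over the list alone: the smooth muscle actin gene Acta2 (4.55-fold, edgeR adjusted p = 0.0102), the matricellular genes Cyr61 (4.01-fold, 0.0147) and Thbs1 (7.91-fold, 0.0289). These 3 calls were each lost without WT A, B or C, and that of Thbs1 also without DNAJ-PKAc A or B, with an adjusted p of at most 0.130. The log2 difference of Thbs1 ran from 2.282, without DNAJ-PKAc C, to 3.245 over all its alternatives. The list was not called (camera adjusted p = 0.603), its mean log2 difference of 0.11 and median of -0.16 differing in sign, its camera test pointing down and its fry test up. The list was split within the fusion group, with medians of -0.45, -0.44 and 0.36 in DNAJ-PKAc A, B and C. Without DNAJ-PKAc C 9 of its genes rose and 16 fell, with a median of -0.46 (camera adjusted p = 0.0717), and without WT B and DNAJ-PKAc C 10 rose and 20 fell (0.0836). In the stellate cell list 1 of 4 rose, Hgf (2.64-fold, 68.2 ± 5.86 to 180 ± 15.3 CPM, SD, n = 3; edgeR adjusted p = 0.00701), Nes was at -2.26 (0.0974), and the list was not called (camera adjusted p = 0.660), with its fry test pointing the other way. Adjusted over that list alone 1 rose and 1 fell, and without DNAJ-PKAc C 1 rose and 3 fell over all genes tested. Leukocyte and endothelial markers had 1 tested gene each, Cd68 at 0.98 (edgeR adjusted p = 0.294) and Eng at -0.70 (0.405). Y-linked genes had 0 CPM in every library. None of the 13 mitochondrially encoded genes of the fixed list was found among the genes counted, so that list could not be analysed.

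Expression along the genome was examined after the gene values had been seen. Over 219 windows of about 40 neighbouring genes (8809 genes with a mean of at least 10 CPM), window medians of the log2 difference had an SD of 0.217, above every permutation of gene positions that was run (highest 0.0932; permutation p = 0.0001, the smallest they can give). Between WT A and WT C, the closest WT pair (r of 0.987), the SD was 0.0508. WT B was not compared in this way. On chromosome 11, from 97.7 to 121.6 Mb, 240 genes had a median of -0.35, with 87.5% below 0 and medians of -0.36, -0.43 and -0.33 in DNAJ-PKAc A, B and C. On chromosome 5, from 110.8 to 135.7 Mb, the median of 160 genes was -0.34. Genes on chromosome 10 from 94.0 to 129.0 Mb had a median of 0.35 and on chromosome 3 from 101.6 to 142.6 Mb one of 0.30. Shifts were not confined to these regions. The rule of 3 neighbouring windows left out windows with larger medians, such as -0.684 on chromosome 1 from 4.8 to 33.9 Mb. Another, on chromosome 6 from 135.2 to 149.3 Mb, had a median of 0.547. Over whole chromosomes the median was -0.27 on chromosome 11, 0.30 on chromosome 10 and -0.19 on chromosome 9. It was 0.19 on chromosome 3 and -0.07 on chromosome 5. A window on chromosome 13, from 21.7 to 23.7 Mb, held 40 Hist1 histone genes among its 42 and was split, at 2.67 and 2.41 in DNAJ-PKAc A and B and -0.87 in C. The 4 regions given first, on chromosomes 11, 5, 10 and 3, held 24 of the 250 placed genes that changed, or 9.6%, and 7.3% of all placed genes.

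**Figure D4:**
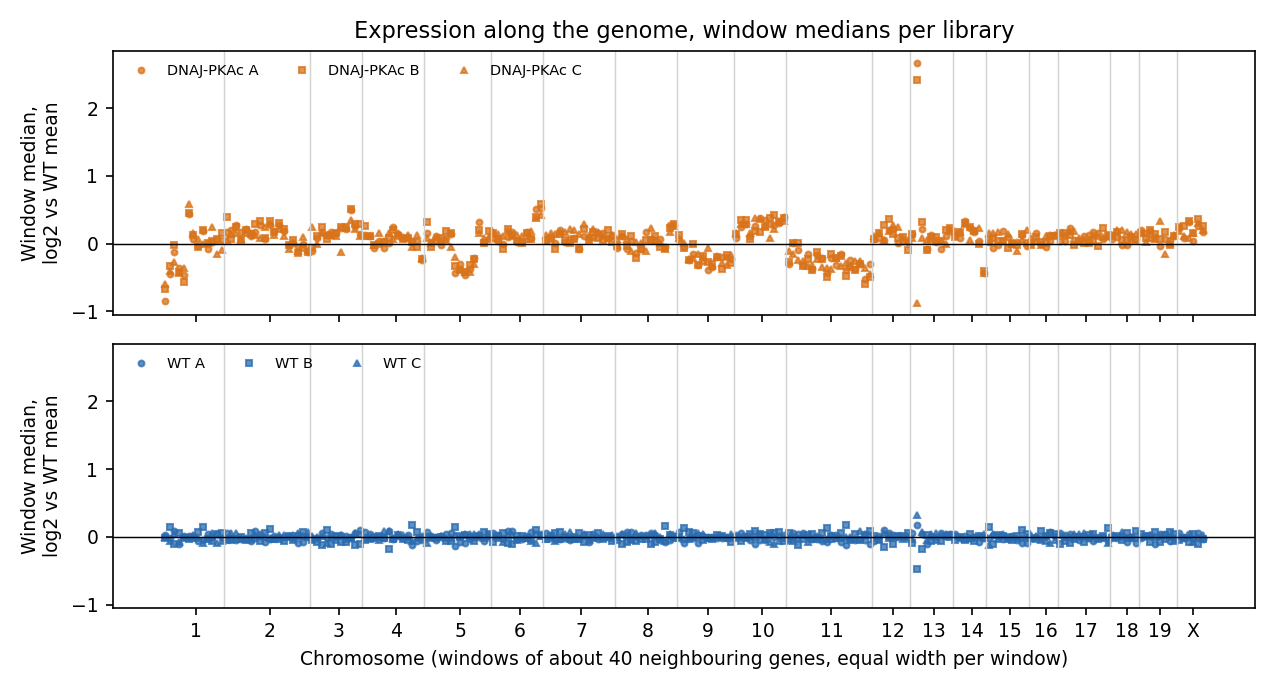
Median log2 CPM minus the WT mean over windows of about 40 neighbouring genes along chromosomes 1 to 19 and X, 1 point per library, with DNAJ-PKAc in the upper panel and WT in the lower. The DNAJ-PKAc libraries share regional shifts, such as medians of -0.36, -0.43 and -0.33 on chromosome 11 from 97.7 to 121.6 Mb, and split at the histone window on chromosome 13.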

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

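Leaving out WT B and DNAJ-PKAc C together and weighting libraries by quality were chosen after the data were seen; the other alternatives were planned. No called gene changed sign under any alternative run for the counts. RLE factors, upper-quartile factors, either other filter, limma-voom, dispersions without the robust option and structural RNA left out gave 385 to 415 genes changed, and 372 of the calls were shared with RLE factors and 347 with upper-quartile factors. DESeq2 gave 974 genes (348 higher, 626 lower; 176 and 417 at least 2-fold). A threshold of 0.01 gave 72 (14 higher, 58 lower; 14 and 58 at least 2-fold). Without 1 library the counts ran from 77 to 2808 for genes changed, 19 to 1587 higher, 51 to 1221 lower, 19 to 640 higher at least 2-fold and 51 to 744 lower at least 2-fold. The highest values all came without DNAJ-PKAc C. Without WT B and DNAJ-PKAc C, 5336 genes changed (2633 higher, 2703 lower; 626 and 842 at least 2-fold). That choice kept the closest pair of each group, so a smaller spread within groups was built into it. Library quality weights, which were 0.25 for WT B, 0.146 for DNAJ-PKAc C and 1.83 to 2.86 for the others, gave 5074 (2757 higher, 2317 lower; 629 and 784 at least 2-fold). With the replicate letter as a block 199 genes changed (56 higher, 143 lower; 56 higher at least 2-fold), of which 181 were among the 385. The letters were not shown to pair the samples: deviations of same-letter libraries correlated at 0.211 for A, -0.198 for B and 0.0282 for C, and not every library correlated best with its own letter. Of 64 named genes called, 19 kept the call in all alternatives run, 45 lost it without at least 1 library, 16 with the block and 7 with another scaling, filter or test. Beyond the built-in spread, the cause of these changes was not tested.

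Prkaca passed the threshold without DNAJ-PKAc C (log2 0.71, adjusted p = 0.0242), without WT B and DNAJ-PKAc C (0.77, 4.9e-05) and with quality weights (0.79, 0.000768); its log2 difference ran from 0.4725 to 0.7117 without 1 library, and over all its alternatives the adjusted p ran from 4.9e-05 to 0.436. Dnajb1, at 0.00, lay below 0 with RLE factors (-0.04021), upper-quartile factors (-0.06826), DESeq2 (-0.04014), limma-voom (-0.03295) and the block (-0.03321), and from -0.1358 to 0.2092 without 1 library. Glul did so with RLE factors (-0.02353), upper-quartile factors (-0.04962), DESeq2 (-0.02332), limma-voom (-0.0006236) and the block (-0.002495), and ran from -0.072 to 0.1842 without 1 library. Asns was at -0.02985 without WT B and DNAJ-PKAc C. None of these values of Dnajb1, Glul and Asns passed the threshold, and the cause was not tested.

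With an estimated correlation 0 lists were higher and 0 lower, and fry gave 7 higher. With fry the calls of serine and one-carbon metabolism (adjusted p = 0.173), nucleotide synthesis (0.274), oxidative phosphorylation (0.173), heat shock (0.274) and cell cycle (0.520) were lost and the urea cycle list was gained (0.0376). Fry does not compare a list with other genes. The serine call was also lost with no filter (0.0608). Lists that were not called changed direction in some alternatives, with these adjusted p: PKA subunits with quality weights (0.9763); glycolysis without DNAJ-PKAc C (0.7714), without WT B and DNAJ-PKAc C (0.7848) and with weights (0.8689); the ATF4 list without WT C (0.7571), without DNAJ-PKAc C (0.4411), without both libraries (0.7848) and with weights (0.9763); the progenitor list with no filter (0.7858); the mesenchymal list without DNAJ-PKAc A (0.9236) or B (0.761) and with fry (0.9773); and the stellate list with fry (0.5392). Without 1 library the adjusted p ran from 0.2807 to 0.7714 for glycolysis, 0.06516 to 0.7571 for the ATF4 list and 0.07167 to 0.9236 for the mesenchymal list. The cause was not tested. Depth limits genes of few counts, such as Afp with 4 counts over the WT libraries and Lphn1 with 4 over the DNAJ-PKAc libraries.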

Other observations

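The tests of the 3 patterns below were chosen after the results were seen, and the splits of the samples were planned; the genes of the next paragraph were chosen after their values were seen.

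Some calls lay outside the lists. Actg2, smooth muscle gamma actin, rose 9.26-fold (edgeR adjusted p = 0.0233), Ankrd1 4.54-fold (0.017), Csrp1 2.24-fold (0.0383) and Srf, serum response factor, 1.69-fold (0.04). Calcrl, which encodes the receptor that pairs with the product of Ramp3, rose 4.51-fold (0.039), and the fatty acid binding protein genes Fabp4 and Fabp5 rose 5.89-fold (0.0317) and 6.59-fold (0.0147). Each of these 7 calls was lost without at least 1 of WT A, B or C or DNAJ-PKAc A or B, with an adjusted p of at most 0.194 (Srf without DNAJ-PKAc A). Ly6e fell from 239 ± 13.6 to 5.27 ± 0.765 CPM (SD, n = 3; log2 -5.50, SE 0.17, edgeR adjusted p = 0.000127), and Ly6a fell 25.5-fold (0.00252). Naip1 and Naip2, inflammasome sensor genes whose paralogs share reads, so that their values are uncertain, fell 11.1-fold (0.0099) and 6.86-fold (0.0133), with an adjusted p of at most 0.0639 without 1 library. Gbp6, which also shares reads, fell 20.1-fold (0.00159), and Gbp7 fell 3.81-fold (0.0263; at most 0.101, without WT A).

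DNAJ-PKAc C stood apart from A and B (r of 0.914 and 0.911, against 0.993 between A and B). Its r with WT A, B and C was 0.928, 0.912 and 0.933. An exchange with a WT library was argued against by 11 genes at 10 CPM or more in WT and under 2% of that in A and B that lay at a median of 1.68% of WT in C (upper quartile 6.62%). Admixed WT RNA would have to make up 79.7% of C to bring the profile closest, far above that level, which argues against it. Cell cycle genes lay at a median log2 of -3.09 in C against the mean of A and B, with 37 of 38 lower. These values are part of the split itself, so they do not test whether that culture proliferated more slowly, which stays open, as do culture density and harvest, which the labels do not record.

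Regional shifts were shared by the 3 DNAJ-PKAc libraries. Chance placing was excluded by permuted positions (p of 1e-04, the smallest they can give). GC content with gene length was argued against by 95.6% of the SD of window medians kept after their correction. That correction was fitted over all genes together, and bias of another form was not tested. Contrasts with no library in common (DNAJ-PKAc A minus WT A, and C minus WT C) had window medians correlated at 0.309 across windows, against a median of 0.168 and a highest of 0.406 with permuted genes (permutation p = 0.0144), and at 0.84 once the histone window, left out after it was seen, was removed (highest permuted 0.385, p of 0.0001). Windows are not independent replicates. A candidate explanation is a difference in DNA copy number between the lines, but DNA was not measured, regional regulation would give the same values, and with 1 line per genotype a difference between lines cannot be separated from an effect of the fusion.

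Interferon response genes were lower in DNAJ-PKAc. Leukocyte RNA in WT was argued against by leukocyte markers that summed to 2.48 CPM in WT and 4.57 CPM in DNAJ-PKAc (Cd68 being the 1 tested), and a single WT library by a list median of -0.854 or lower without any of them. Copy loss as broad as the windows of neighbouring genes was argued against as the whole cause. Over 28 placed genes the median was -0.778 once window medians were taken off (bootstrap interval -1.5 to -0.605). A loss confined to single genes or small clusters would not move a window median, so it was not tested. The interval takes the genes as independent, whereas the estimated correlation within the list was 0.433. A lower basal interferon tone in the DNAJ-PKAc line may remain as a hypothesis, untested against differences between lines or cultures.

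The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 385 genes changed, 150 higher and 235 lower, with 105 and 209 at least 2-fold. The highest other split gave 0 of each. Every other split mixes the genotypes and so puts their difference into the spread within groups. Few calls there are built in and do not speak for the real split. The real split gave 11 lists higher and 3 lower. A split and its mirror are one, so the other splits have no direction of their own, and the larger of their 2 list counts was set against each of these: the highest was 7. For each of these results but the lists lower, 1 split, the real one, gave a result as large. For the lists lower 9 splits, the real one included, had 3 or more lists in at least 1 direction.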
